A study of Mus musculus with 12 samples.

How the data were processed

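Total RNA of splenic B cells was profiled on 12 one-colour miRNA microarrays. Per the labels' protocols, spleens of mice carrying the CD19-Cre knock-in allele were depleted of erythrocytes and stained for B220, CD21 and CD23, and 2 B-cell types were sorted, follicular (FO) and marginal zone (MZ) cells, and their RNA extracted with TRIzol. The mice carried either 1 floxed and 1 intact Dicer allele (control) or 2 floxed alleles (here called Dicer-deleted). CD19-Cre recombines floxed alleles in the B lineage, and Dicer cuts precursor hairpins into mature miRNAs. Each of the 4 groups of cell type and genotype holds 3 arrays. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

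Per the labels' protocols, 120 ng of RNA per array was dephosphorylated and ligated at the 3' end to a Cy3-labelled nucleotide, and was hybridised to an Agilent mouse miRNA array. Per the file headers, the arrays were read with Feature Extraction 9.5.3.1, while the submitters' processing notes name version 10.1.1. The deposited scanner tables give intensity on a linear scale for every spot: a processed signal after background subtraction, a mean signal with its local background, and a total signal per miRNA. Per the file headers, the array MZ control replicate 1 has no second scan at low gain, with a scaling slope of 1 against 19.5 to 20.0 on the other arrays; no miRNA spot was saturated on any array. The authors' deposited matrix holds values on the log2 scale. These equalled the mean log2 processed signal per miRNA minus 1 constant per array on 11 of the 12 arrays, with a SD around the constant of 0.142 on MZ Dicer-deleted replicate 1. They were not centred per miRNA, and the column medians lay between -1.82 and -0.58. How the constant was chosen stays unknown, and 18 values were missing.

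The array design lists 577 miRNAs, of which 567 are mouse and 10 are from a mouse gammaherpesvirus, measured by 1712 probes and 11540 spots. The main values were made from the processed signal. Control spots and outlier-flagged spots (256 to 423 per array) were left out, spots of one probe were averaged, and each array was divided by its 75th percentile over the 86 probes detected on all 12 arrays. Different probes of one miRNA were averaged on the linear scale. Values under a floor of 0.0190, the median over arrays of the lowest scaled signal of a detected probe, were set to it before taking log2 (-5.72). Values at the floor have no order, and a fold change that ends there can understate the difference. On both MZ replicate 1 arrays, where the lowest detected signal was -2.66 (control) and -3.50 (Dicer-deleted) and lay above the floor, it can also overstate it. A probe counted as detected where at least 50% of its spots were well above background, and a miRNA where any of its probes was. The 162 mouse miRNAs detected on all 3 arrays of at least 1 group were tested. Where a miRNA had no probe well above background on any array of a group, the fold is a bound, "at least N-fold", against the mean of each array's lowest detectable signal or the probe's own signal, whichever was higher, and none is given where that bound is under 1. Among miRNAs with several detected probes, the probes disagreed in sign for 13 miRNAs in MZ against FO controls, 9 in Dicer-deleted against control FO cells, 27 in the same comparison of MZ cells and 21 in MZ against FO Dicer-deleted cells.

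Differences were tested with limma 3.58.1 in R 4.3.3 (files were read with version 1.17.8 of the data.table package), with lmFit and eBayes in one fit of 4 group means over all 12 arrays, and with Benjamini-Hochberg adjustment over the 162 miRNAs at 0.05. All p-values are two-sided, and all adjusted p-values for miRNAs come from limma. The contrasts were MZ against FO in controls, Dicer-deleted against control in FO and in MZ cells, MZ against FO in Dicer-deleted cells, the difference between both genotype effects (interaction), and their mean. Lists of miRNAs were tested with camera, which compares a list with all other tested miRNAs, at a preset inter-miRNA correlation of 0.01 and with Benjamini-Hochberg adjustment over lists. Camera with a correlation estimated from the residuals was the alternative, and with it no list passed in any contrast. Summed signal and the number of detected miRNAs were compared by exact permutation tests, with genotype permuted within cell type. With 3 arrays against 3, such a test cannot give a p under 0.1. The number of arrays limits the precision of every value.

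The groups, tests, contrasts, 23 lists, naming rule and most of the other settings named below were fixed before the data were examined. The lists held the miR-17 to miR-92a cluster, the miR-106a-363 and miR-106b-25 clusters, the let-7, miR-15/16, miR-29, miR-30, miR-181 and miR-26 families, the miR-23-27-24 clusters, the miR-99/100 and miR-125 families, the miR-221, miR-222 and miR-146 families, miRNAs with described B-cell roles, and T-cell-associated, myeloid and platelet, erythroid, and stromal and endothelial markers. Others held miRNAs of non-canonical biogenesis, the entries numbered miR-680 to miR-721, star strands, the imprinted Dlk1-Dio3 region, an embryonic stem cell cluster, miRNAs restricted to other tissues, and viral miRNAs. The 12 lists with at least 3 tested members were tested, and the others are given by their tested members. The text names, per contrast, up to 12 miRNAs with the largest rise and 12 with the largest fall among those past the threshold whose groups do not overlap, a fixed set of 17 miRNAs including miR-150, miR-155, miR-451, miR-223, let-7a and miR-34a, and up to 4 members per list with the smallest p. MiRNAs named outside this rule are marked as chosen after their values were seen.

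The labels give the groups shared replicate numbers. Same-numbered arrays deviated together from their group means, with correlations over miRNAs of 0.65, 0.57 and 0.54 between MZ and FO controls, of 0.94, 0.79 and 0.83 between Dicer-deleted and control FO cells, and of 0.86, 0.79 and 0.50 between the MZ genotypes. For MZ against FO Dicer-deleted cells they were 0.39, 0.86 and -0.24. Arrays of different numbers deviated together as strongly or more so in 4 cases: the highest such correlation was 0.68 for replicate 3 of MZ and FO controls, 0.89 for replicate 2 of the FO genotypes, 0.50 for replicate 3 of the MZ genotypes and 0.14 for replicate 3 of MZ and FO Dicer-deleted cells. Replicate 1 arrays, which share slide 2, were thus set apart from the others, and replicates 2 and 3 were not clearly told from each other. By a rule of same-number correlations above 0.1, the numbers were treated as pairing the first 3 comparisons, and the fit with the replicate number as a block is given where it changes a call. The arrays lay on 2 slides. Slide 1 held 7 arrays from all 4 groups, and slide 2 held 5, namely the replicate 1 arrays of every group and MZ Dicer-deleted replicate 3. There were 3 scans, of which 1 held slide 1 and another held only MZ Dicer-deleted replicate 1.

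The analysis was repeated with other choices of scaling, background correction (normexp with offset 50), filter, floor, probe summary, source values, variance model, samples in the fit and slide, and without each array in turn. The fits without both MZ replicate 1 arrays and with scan as a block, and the exact sign-flip tests of summed signal and detected miRNAs within same-number pairs, were chosen after seeing the data. The procedure was tested on simulated values of the 162 miRNAs, 20 runs per contrast. For MZ against FO controls, 28.5%, 53.5% and 74.0% of log2 changes of 1, 2 and 3 were recovered, and 31.0%, 55.5% and 77.0% for the genotype contrast in FO cells. The shares were 24.0%, 56.5% and 68.0% in MZ cells and 24.5%, 45.5% and 68.0% for MZ against FO Dicer-deleted cells. With the replicate block, 39.0%, 65.5% and 85.0% were recovered for MZ against FO controls. A list of 8 miRNAs shifted by -1, tested alone at an unadjusted camera p under 0.05, was called in 100% of runs. Noise was drawn independently per miRNA, whereas the correlation estimated for the 8 let-7 members was 0.86. The simulation thus does not show how often lists are called falsely.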

Results

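The arrays asked which miRNAs distinguish marginal zone from follicular B cells of the mouse spleen, and how loss of Dicer in the B lineage changes miRNA levels in each. Follicular B cells recirculate through lymphoid follicles, while marginal zone B cells stay at the border of the splenic white pulp and respond rapidly to blood-borne antigens. Values are log2 signals scaled within each array, with n = 3 arrays per group. Dicer mRNA is not measured by these arrays, so deletion of the targeted gene could not be checked here.

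Control FO cells had 190 ± 9.71 detected mouse miRNAs per array (mean ± SD, n = 3), Dicer-deleted FO cells 167 ± 10.5, control MZ cells 119 ± 64.3 and Dicer-deleted MZ cells 151 ± 81.5. Both MZ replicate 1 arrays had the fewest, 45 (control) and 70 (Dicer-deleted), against 150 to 233 on the other 10 arrays, of which Dicer-deleted MZ replicate 3 had the most. On both replicate 1 arrays the lowest detectable signals were also the highest, at -2.66 and -3.50 on the scaled log2 axis against -6.54 to -5.35 elsewhere. Within groups, arrays of replicates 2 and 3 correlated at 0.95 to 0.99 over miRNAs, and replicate 1 arrays correlated with them at 0.57 to 0.86. A few entries took most of the signal: on average miR-720 gave 30.9% of it, miR-1224 15.2%, miR-690 11.5%, miR-142-3p 4.64% and miR-494 3.59%. MiR-720 was later recognised as a transfer RNA fragment, and miR-142-3p is abundant in all blood cell lineages.

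**Figure D1:**
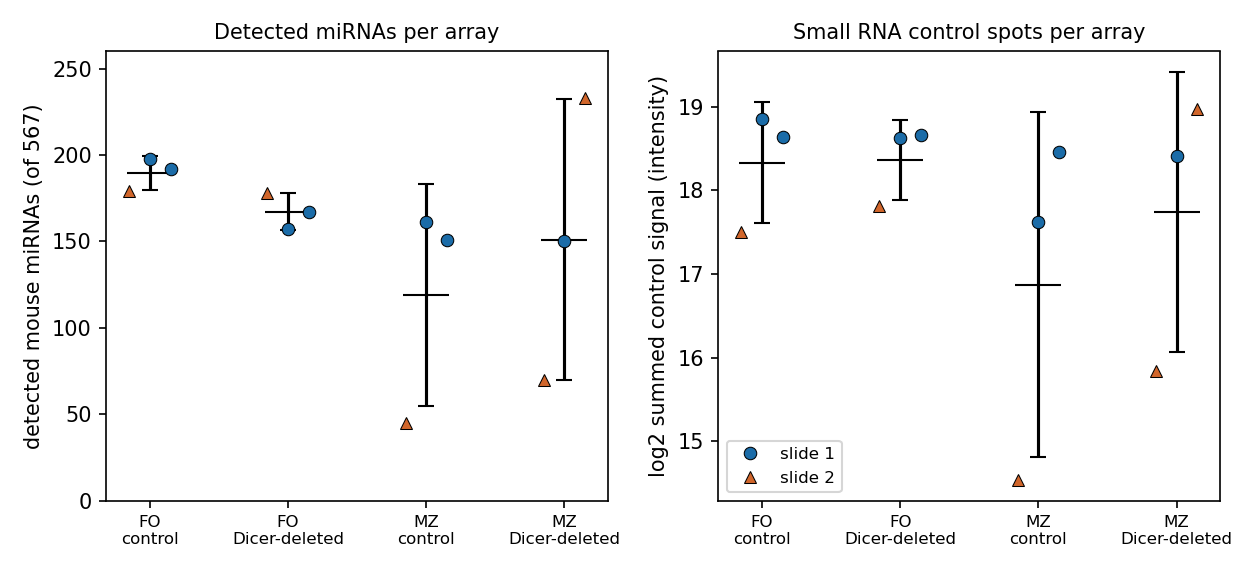
Number of detected mouse miRNAs (left) and log2 summed intensity of the small RNA control spots (right) on each of the 12 arrays, by group. Horizontal bars are means, vertical bars SDs (n = 3), circles slide 1 and triangles slide 2; the MZ replicate 1 arrays have 45 and 70 detected miRNAs and the lowest control signals, 14.53 and 15.83.

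In control mice, the scaled signals of miR-139-5p, miR-28 and miR-200c were lower in MZ than in FO cells. MiR-139-5p was -3.99 ± 0.44 (mean ± SD, n = 3) in FO cells and not well above background on any MZ array, a difference of at least 1.64-fold (limma log2 -1.73, SE 0.24, adjusted p = 0.00935). MiR-28, which restrains germinal centre B-cell proliferation, differed by -1.26 (SE 0.24, adjusted p = 0.0462), and miR-200c, best known from epithelia, by -1.12 (SE 0.23, adjusted p = 0.0462). Both were detected on 1 of 3 MZ control arrays. Every MZ array had the averaged signal of all 3 miRNAs at the floor, so these arrays added no spread to the SEs. No value can lie below the floor, so being lower in MZ in all 3 numbered pairs adds no support. MiR-139-5p, miR-28 and miR-200c were the 3 of 162 miRNAs past the threshold, all lower in MZ, and 22 had an unadjusted p under 0.05. In a limma fit of only the groups compared none passed, with adjusted p = 0.194 for miR-139-5p and 0.257 for both others. In the files' coordinates, whose genome build is not named, the miR-139-5p target lies on chromosome 7 between 108623902 and 108623917, that of miR-28 on chromosome 16 between 24827957 and 24827975, and that of miR-200c on chromosome 6 between 124668342 and 124668356.

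With the replicate number as a block, 36 miRNAs passed, 33 lower and 3 higher in MZ cells; the pairing of replicates 2 and 3 behind this fit is uncertain. MiR-150, the most abundant miRNA of resting mature lymphocytes and a regulator of Myb, had the largest fall, -4.29 (SE 1.07, adjusted p = 0.0424; 0.111 without the block), from 1.18 ± 0.42 in FO to -3.11 ± 2.21 in MZ cells. All 5 members of the miR-23-27-24 clusters fell under the block, by 2.48 for miR-23a (adjusted p = 0.00644), 1.93 for miR-27a, 1.64 for miR-24, 1.37 for miR-23b and 1.05 for miR-27b. So did all 8 tested members of the let-7 family, whose level rises as cells differentiate, from -0.78 for miR-98 to -2.30 for let-7g; without both MZ replicate 1 arrays these were -0.70 and -0.88. Of the miR-17 to miR-92a cluster, which promotes survival of developing B cells, miR-17 (-0.94, adjusted p = 0.0495) and miR-19a (-1.71, adjusted p = 0.0472) passed. MiR-26b (-2.65) and miR-342-3p (-1.57), chosen after their values were seen, passed too. The 3 higher in MZ were miR-877* (1.82), miR-483* (1.52) and miR-188-5p (0.67), the last chosen after its value was seen. These rises rested largely on MZ control replicate 1, being 1.01, 0.63 and 0.36 without both MZ replicate 1 arrays. Most falls shrank there too, to -1.62 for miR-23a, -1.20 for miR-27a, -0.64 for miR-23b, -0.35 for miR-27b, -1.53 for miR-26b and -3.06 for miR-150. Without the block none of these passed; miR-155 (-0.98, SE 0.74), miR-181a (-1.57, SE 0.78), miR-21 (-2.33, SE 1.42) and miR-29a (-1.02, SE 1.19) passed in neither fit.

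**Figure D2:**
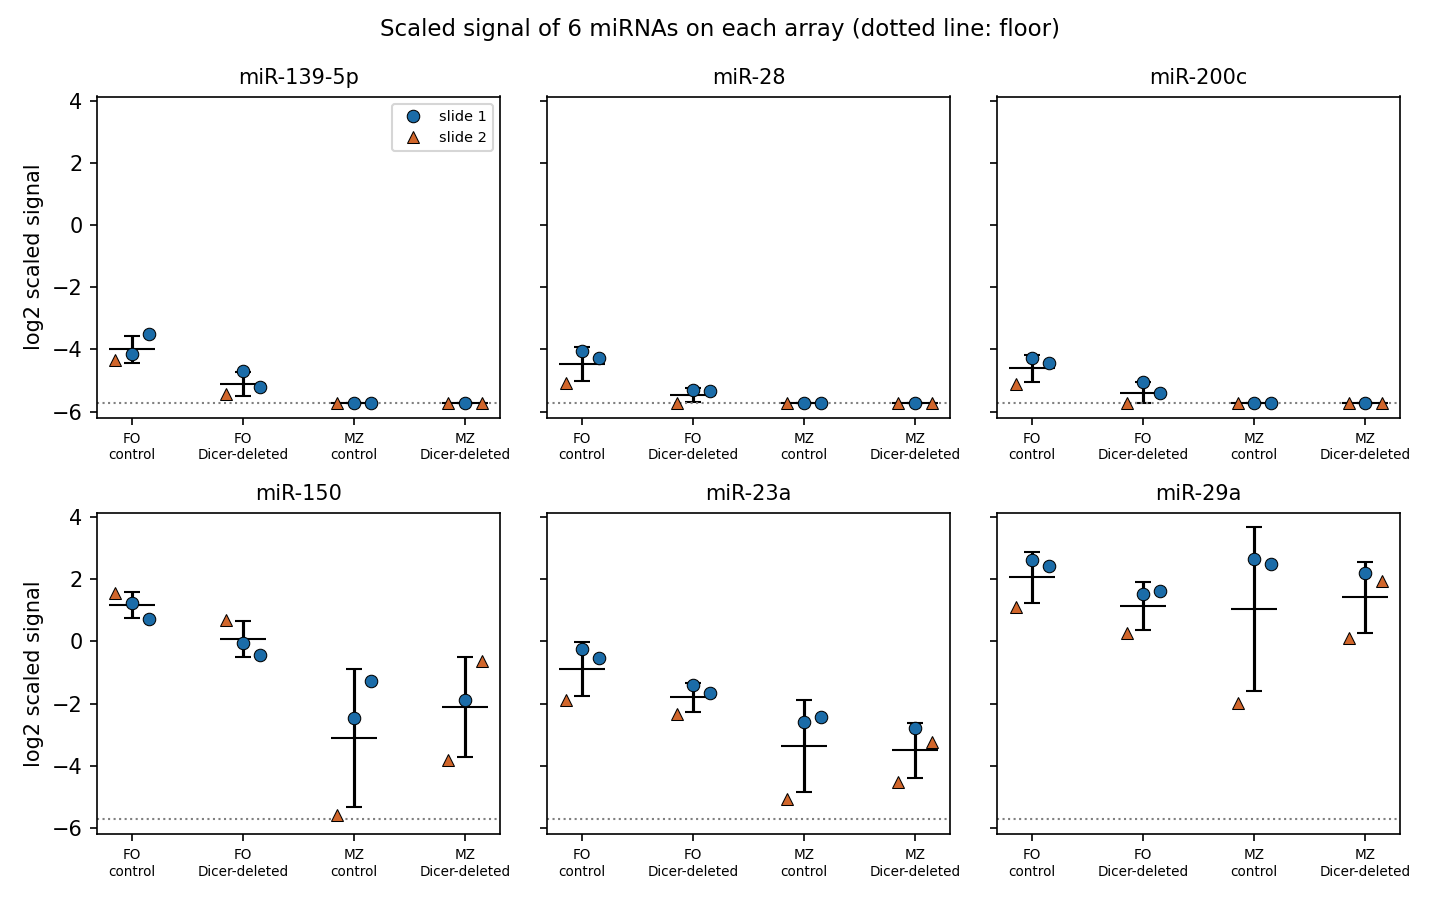
Scaled log2 signal of 6 miRNAs on each array, by group, with mean and SD bars (n = 3), circles for slide 1, triangles for slide 2 and a dotted line at the floor of -5.72. MiR-139-5p, miR-28 and miR-200c lie at the floor on all 6 MZ arrays; miR-150 averages 1.18 in control FO and -3.11 in control MZ cells.

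Taken as lists, the let-7 family (8 of 8 members lower, median -1.55, camera adjusted p = 0.00234) and miRNAs with described B-cell roles (14 of 14 lower, median -1.42, adjusted p = 0.000616) ranked below the other miRNAs in MZ controls. Of these, 0 let-7 members and 1 B-cell miRNA passed over all miRNAs, and 3 and 5 adjusted over the list alone. The miR-23-27-24 clusters (median -1.64, adjusted p = 0.0248; 2 of 5 members adjusted over the list alone), the miR-15/16 family (-1.76, adjusted p = 0.0441; 1 of 5) and the miR-17 to miR-92a cluster (-1.32, adjusted p = 0.0441; 1 of 6) ranked low as well. With the replicate block, the miR-15/16 family (adjusted p = 0.129) and the miR-17 to miR-92a cluster (adjusted p = 0.0843) no longer passed. Ranked high were the entries numbered miR-680 to miR-721, many of them found by early small RNA cloning (median 0.31, adjusted p = 7.67e-05), miRNAs of non-canonical biogenesis (0.30, adjusted p = 0.0248), such as the mirtron miR-1224 (0.75, SE 0.40), and star strands (median 0, mean -0.02, adjusted p = 0.0441). Without the block no member of these 3 lists passed by itself, over all miRNAs or adjusted over the list alone. With an estimated correlation, all 8 calls were lost, with adjusted p = 0.0832 for miR-680 to miR-721, 0.259 for non-canonical biogenesis, 0.269 for star strands and 0.321 for the others. The miR-106a-363 and miR-106b-25 clusters (-1.66, adjusted p = 0.0516), the miR-29 (-1.18, adjusted p = 0.826) and miR-30 (-1.21, adjusted p = 0.201) families and T-cell-associated miRNAs (-1.39, adjusted p = 0.0843) did not pass.

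These calls rest on few arrays. All 3 FO control means lie below the lowest detectable signal of MZ control replicate 1, so that array could not have shown these miRNAs. Without both MZ replicate 1 arrays limma called 0 miRNAs (20 at an unadjusted p under 0.05); leaving out MZ control replicate 2 or 3 alone also gave 0, and the adjusted p of miR-139-5p was then 0.0550 or 0.0547. Slide as a block gave 12 miRNAs, all lower, slide 1 alone 29 (28 lower) and slide 2 alone, with 1 array per control group, can say little about single miRNAs (0 called, 3 at an unadjusted p under 0.05). The scaling set the overall level: all tested miRNAs had a median of -0.43, against -1.25 unscaled, -0.54 with the percentile over all probes, -0.21 after quantile normalization and 0.69 with normexp. Relative to that median, let-7 lay at -1.12, -1.54, -1.18, -0.76 and -1.27. The unscaled medians of miR-680 to miR-721, non-canonical and star lists turned negative (-0.90, -0.66 and -0.38), and relative to all miRNAs stayed positive (0.36, 0.60 and 0.87). Let-7 ranked low within slide 1 (-1.06, adjusted p = 0.00847) and without both MZ replicate 1 arrays (-0.75), where the medians shrank to -0.65 for B-cell roles, -1.003 for miR-23-27-24 and -0.62 for miR-15/16, and that of miR-29 turned to 0.50; slide 2 compares 1 FO array with the dim MZ array (-2.65). Without MZ control replicate 1 the miR-17 to miR-92a (adjusted p = 0.106), miR-15/16 (adjusted p = 0.0893), non-canonical (adjusted p = 0.0761) and star strand (adjusted p = 0.0893) calls were lost. Without FO control replicate 3 only 4 of the 8 calls stayed, and that of the miR-23-27-24 clusters was among those lost (adjusted p = 0.0504). Leaving out FO control replicate 2 or MZ control replicate 3 left 5 calls each. Among the 12 arrays left out in turn, miR-28 lost its call in 9 cases (adjusted p up to 0.167), miR-200c in 10 (up to 0.209) and miR-139-5p in 2.

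In FO cells, Dicer deletion went with lower let-7 levels. All 8 tested let-7 members were lower in Dicer-deleted than in control FO cells, with a median log2 difference of -1.30 (camera adjusted p = 0.000116), for instance let-7b from -1.87 ± 0.42 to -3.23 ± 0.27 and let-7c from -1.53 ± 0.33 to -2.82 ± 0.20 (mean ± SD, n = 3). MiRNAs with described B-cell roles were lower in 14 of 14 cases (median -0.91, adjusted p = 0.000999), among them miR-17 (-0.84, SE 0.24), miR-185 (-0.70, SE 0.24), miR-155 (-0.997, SE 0.74) and miR-150 (-1.11, SE 1.09). The 6 members of the miR-17 to miR-92a cluster were also lower (median -0.85, adjusted p = 0.0102) and did not pass within slide 1 (-1.04, adjusted p = 0.0720), where let-7 and B-cell roles (adjusted p = 0.00154 for both) and miR-680 to miR-721 (adjusted p = 0.000124) did. The entries numbered miR-680 to miR-721 ranked high, with 21 of 22 above 0 (median 0.37, adjusted p = 0.000116), such as miR-705 (0.74, SE 0.34) and miR-712 (0.50, SE 0.23). With an estimated correlation none of these 4 lists passed, with adjusted p = 0.281 for let-7 and miR-17 to miR-92a, 0.374 for B-cell roles and 0.103 for miR-680 to miR-721.

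No single miRNA passed limma's threshold in FO cells: 0 of 162, with 11 at an unadjusted p under 0.05 and a smallest adjusted p of 0.199. The residual spread of this fit was shared by all groups, so it included that of both MZ replicate 1 arrays. Without these, in a fit chosen after seeing the data, limma again called 0, with 33 at an unadjusted p under 0.05. Adding slide as a block there gave 29, of which 25 were lower. The count of 0 over all arrays thus does not show that FO cells changed little. With the replicate block, whose pairing is equally uncertain here, 8 passed, all lower after deletion: let-7b (-1.36, SE 0.26), let-7c (-1.29, SE 0.27), miR-27a (-1.16, SE 0.23), miR-28 (-0.996, SE 0.21) and miR-98 (adjusted p = 0.0422 each), and miR-139-5p (-1.12), miR-532-5p (-0.84) and miR-140 (-0.88, adjusted p = 0.00839), the last 3 chosen after their values were seen. MiR-98, a let-7 member, was not well above background on any Dicer-deleted FO array and was at least 1.85-fold higher in controls (log2 -0.94). Adjusted over the list alone, 3 let-7 members, 2 miRNAs with B-cell roles and 1 of the miR-17 to miR-92a cluster passed without the block. MiR-142-3p (-1.19, SE 2.73), miR-21 (-1.33, SE 1.42), miR-16 (-0.85, SE 0.70), miR-29a (-0.92, SE 1.19) and miR-181a (-0.32, SE 0.78) passed in neither fit. Under the block the miR-23-27-24 clusters (median -0.91; adjusted p = 0.0646 without, 0.0201 with it) and star strands (0.13; 0.0646 and 0.0481) passed as well. The miR-106a-363 and miR-106b-25 clusters (-0.89), the miR-15/16 (-0.62), miR-29 (-1.05) and miR-30 (-0.99) families, T-cell-associated (-0.33) and non-canonical (0.39) miRNAs passed in neither.

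**Figure D3:**
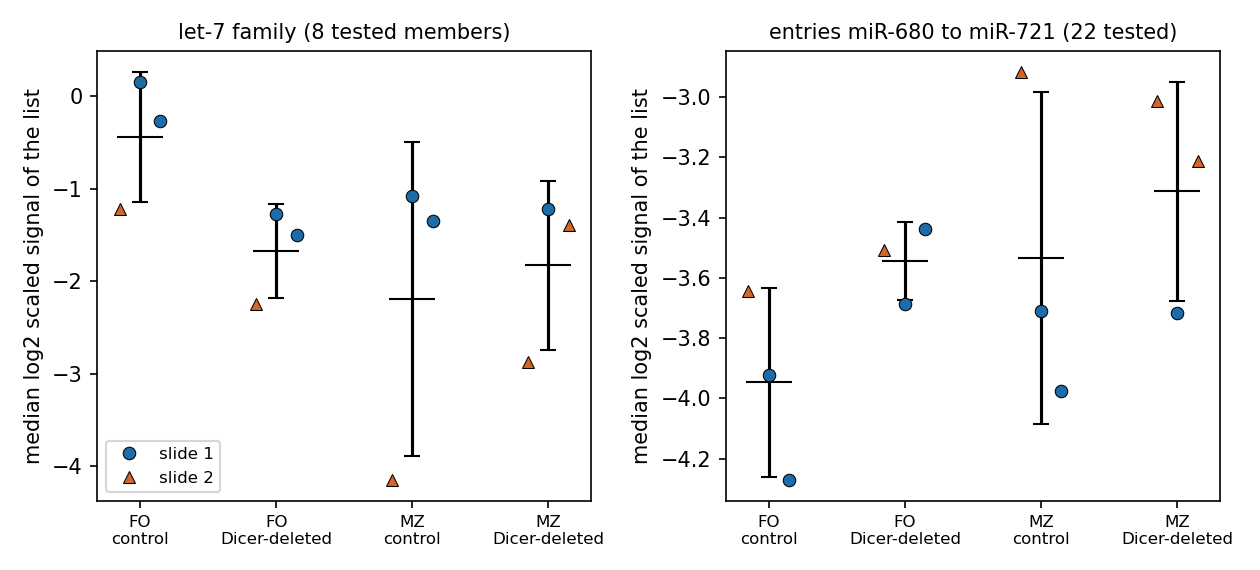
Median scaled log2 signal of the 8 tested let-7 members (left) and of the 22 tested entries numbered miR-680 to miR-721 (right) on each array, by group, with mean and SD bars (n = 3), circles for slide 1 and triangles for slide 2. The let-7 median is higher on each control FO array than on the Dicer-deleted FO array of the same number, and unscaled the fitted difference of the miR-680 to miR-721 list in FO turns from 0.37 to -0.17.

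The FO counts moved with the arrays used. Slide as a block gave 0 miRNAs (26 at an unadjusted p under 0.05), slide 1 alone 19 (16 lower, 3 higher) and slide 2 alone had 1 array per group; leaving out FO control replicate 1 gave 4, and leaving out MZ control replicate 1 gave 2. The let-7 median was -1.35 within slide 1 and -1.01 within slide 2. All tested miRNAs had a median of -0.02, against -0.42 unscaled, and relative to it let-7 lay at -1.28 and -1.46, and miR-680 to miR-721 at 0.39 and 0.26.

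Total signal did not separate the genotypes in either cell type by tests that leave the replicate numbers aside. It is mostly that of a few entries and says little about the other miRNAs. The 5 brightest entries of each array gave 50.7% to 61.1% of it on control FO and 68.4% to 72.3% on Dicer-deleted FO arrays. On MZ arrays the ranges overlapped, 63.8% to 87.8% (control) and 59.9% to 84.5% (Dicer-deleted). The log2 summed miRNA signal of FO cells was 15.65 ± 0.18 after deletion and 16.18 ± 0.63 in controls, a difference of -0.53 (exact permutation p = 0.3), and that of MZ cells differed by 0.66 (exact permutation p = 0.6). Over both cell types it differed by 0.06 (exact permutation p = 0.895, 400 arrangements). Detected miRNAs differed by -22.3 in FO (exact permutation p = 0.1, the smallest possible), by 32 in MZ (exact permutation p = 0.7) and by 4.83 over both (exact permutation p = 0.925). By number, the summed signal was lower after deletion in all 3 FO pairs and higher in all 3 MZ pairs (0.36 to 0.81), with exact sign-flip p = 0.25 in each, the smallest possible. The difference between the cell types was 1.19 (exact sign-flip p = 0.0312, the smallest possible, and exact permutation p = 0.37 without pairs), a test chosen after seeing the data on an uncertain pairing. Detected miRNAs were lower in all 3 FO pairs and in 1 of 3 MZ pairs. Within slide 1 the pooled differences were -0.31 for the summed signal and -19.5 for detected miRNAs. Without scaling, the median difference of all tested miRNAs was -0.42 in FO and 0.52 in MZ cells; the latter was -0.13 in the lowest and 1.29 in the highest case when 1 array was left out.

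In MZ cells, neither a miRNA nor a list passed for genotype in the fit of group means, while lists passed in 9 of 35 other settings, not all in 1 direction. Slide 2, 1 of these settings, holds only the dim replicate 1 array as MZ control, so it cannot support a call. Limma called 0 of 162 miRNAs, with 0 at an unadjusted p under 0.05, and with the replicate block also 0 (3 unadjusted). All 8 let-7 members had positive differences (median 0.46, camera adjusted p = 0.138), which turned to -0.24 with normexp, where all tested miRNAs shifted from 0.12 to -0.26 and let-7 lay 0.01 above them. Let-7 passed as higher with slide as a block (0.83, adjusted p = 0.00929), quantile normalization (0.53, adjusted p = 0.0377), no filter (0.36, adjusted p = 0.000585), and without MZ control replicate 2 (0.94, adjusted p = 0.00152) or Dicer-deleted MZ replicate 3 (0.32, adjusted p = 0.00922). It did not pass without both MZ replicate 1 arrays (-0.00866, camera adjusted p = 0.982). Its median was 1.94 within slide 2, with 1 control array, and 0.07 within slide 1, with 1 Dicer-deleted MZ array. B-cell roles passed as higher with no filter (0.12, adjusted p = 0.000354), and their median within slide 2, with 1 control array, was 1.81. Without MZ control replicate 1, B-cell roles (-0.56, adjusted p = 0.0410) and the miR-23-27-24 clusters (-0.81, adjusted p = 0.00621) passed as lower. MiR-146a, a brake on innate signalling, differed by 1.13 (SE 0.58, adjusted p = 1), miR-150 by 1.01 (SE 1.09), miR-16 by 0.68 (SE 0.70), miR-155 by 0.55 (SE 0.74) and miR-92a by -0.49 (SE 0.27). B-cell roles (median 0.32), the miR-15/16 (0.68), miR-29 (0.58) and miR-30 (0.25) families, the miR-17 to miR-92a (0.31), miR-106a-363 and miR-106b-25 (0.26) and miR-23-27-24 (-0.11) clusters, T-cell-associated (0.50) and non-canonical (-0.12) miRNAs, star strands (0.05) and miR-680 to miR-721 (-0.03) all had camera adjusted p of 0.138 or more. Slide as a block called 0 miRNAs (4 unadjusted) and slide 1 alone 0 (6 unadjusted).

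The genotype difference of 3 lists differed between MZ and FO cells by camera on the interaction. The let-7 family had a median interaction of 1.71 (8 of 8 members positive, adjusted p = 2.24e-05; 1.36 within slide 1), B-cell roles 1.19 (14 of 14 positive, adjusted p = 0.00265), and miR-680 to miR-721 -0.37 (20 of 22 negative, adjusted p = 2.24e-05). With an estimated correlation the adjusted p was 0.344, 0.436 and 0.0724. Without MZ control replicate 1 the B-cell list lost its call (0.38, adjusted p = 0.139). Without both MZ replicate 1 arrays the let-7 median shrank to 1.19 and stayed called (camera adjusted p = 3.68e-05). The median interaction of all tested miRNAs was 0.20, against 1.15 unscaled; unscaled, miR-680 to miR-721 turned to 0.75, and relative to all miRNAs it was -0.40. Limma called 0 single miRNAs (10 at an unadjusted p under 0.05; 26 with the replicate block), among them miR-17 (1.09, SE 0.34, adjusted p = 0.501), let-7b (1.55, SE 0.51, adjusted p = 0.501) and let-7a (1.79, SE 0.78, adjusted p = 0.773). With the block the star strands passed too (-0.10, adjusted p = 0.0434). Adjusted over the list alone, 0 let-7 members passed without and 5 of 8 with the block.

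Averaged over both cell types, limma called 0 miRNAs for genotype (9 at an unadjusted p under 0.05, 27 with the replicate block). MiR-451, an erythroid miRNA matured by Ago2 without Dicer, was higher after deletion by 1.53 (SE 0.96) in FO and 1.80 (SE 0.96) in MZ cells, with a mean of 1.66 (SE 0.68, adjusted p = 0.859). MiR-28 (-0.50, SE 0.17) and miR-92a (-0.52, SE 0.19) had adjusted p = 0.859 each. The let-7 family (median -0.35), B-cell roles (-0.28), the miR-17 to miR-92a cluster (-0.33) and miR-680 to miR-721 (0.17) passed camera (adjusted p = 0.00957 each), and not with an estimated correlation (adjusted p = 0.533, 0.533, 0.466 and 0.466) or with slide as a block (adjusted p = 0.0790, 0.115, 0.0747 and 0.0557). None of the 4 passed without MZ control replicate 2 (adjusted p = 0.108 each), MZ control replicate 3 or Dicer-deleted MZ replicate 1 (adjusted p from 0.0593 to 0.182), nor with quantile normalization, the deposited log2 values or scan as a block. Under the replicate block B-cell roles and miR-17 to miR-92a no longer passed (adjusted p = 0.0813 each) and the miR-23-27-24 clusters did (-0.53, adjusted p = 0.0204). The genotype differences of MZ and FO cells correlated at -0.20 across 162 miRNAs (Spearman -0.25), which are not independent replicates; without MZ control replicate 1 the correlation was 0.71.

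Between Dicer-deleted MZ and FO cells, limma called 0 miRNAs (3 at an unadjusted p under 0.05). The largest differences among the named miRNAs were those of miR-150, -2.18 (SE 1.09), miR-23a, -1.71 (SE 0.77), and miR-181a, -1.56 (SE 0.78), each with all MZ arrays below all FO arrays (adjusted p = 1). No list passed: let-7 had a median of 0.22 (adjusted p = 0.0895) and miR-23-27-24 of -0.76 (adjusted p = 0.0871), with all 5 members lower. Lists passed in 16 of 35 other settings, among them let-7 as higher with slide as a block (0.51, adjusted p = 0.00282) and within slide 1 (0.41, adjusted p = 0.00489). By the correlation rule the replicate numbers were not treated as pairing these arrays, since those of replicate 3 correlated at -0.24. That MZ array lay on slide 2 and that FO array on slide 1, so whether the numbers pair these cells stays unknown. Slide as a block called 0 miRNAs (7 unadjusted) and slide 1 alone 0 (16 unadjusted).

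Myeloid, platelet, stromal and endothelial markers were sparse on these arrays. Of 6 myeloid and platelet markers only miR-223 was tested, near -4.65 ± 0.69 in control FO cells, and it differed by -0.17 (SE 0.51) between MZ and FO controls and by -0.36 (SE 0.51) and 0.58 (SE 0.51) with genotype in FO and MZ. Of 3 erythroid markers, miR-451 and miR-486 were tested. MiR-486 was higher after deletion by 0.43 (SE 0.24) in FO cells, and miR-451 was higher in both cell types, as given above. Whether these differences reflect the content of erythroid cells was not tested. Of 14 stromal and endothelial markers on the array, miR-10a and miR-214 were tested, with genotype differences of -0.06 (SE 0.10) and 0.46 (SE 0.38) in FO cells. None passed the threshold in any contrast.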

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

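The effect of genotype on let-7 differed between the cell types by a test of the difference itself, with a median interaction of 1.71, lost with an estimated correlation (adjusted p = 0.344). That median was 1.19 without both MZ replicate 1 arrays. Of the tests that follow, that of array brightness was written before its result was seen and the others after. With each array's summed signal as a covariate, over 10 arrays, the mean let-7 difference in FO cells was -0.98 (SE 0.32). Without the covariate it was -1.24 (SE 0.32), so most of the fall remained after this adjustment. The test cannot decide on array brightness. Summed signal is mostly that of a few entries, and both control FO arrays of slide 1 were the brightest of that slide. Slide is argued against, since the median within slide 1 was -1.35 with the highest member at -1.12. So is a fall in MZ cells hidden by both dim replicate 1 arrays. Without them the MZ median was -0.00866 with the lowest member at -0.28. Unequal deletion or turnover of mature miRNAs in both cell types may be a source and was not tested here, and chance, with 3 arrays per group, stays open.

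The same test set apart miRNAs with described B-cell roles, with a median interaction of 1.19, and the entries numbered miR-680 to miR-721, with a median of -0.37. With an estimated correlation neither passed (adjusted p = 0.436 and 0.0724). Without MZ control replicate 1 the B-cell roles were not called (0.38, adjusted p = 0.139), and unscaled miR-680 to miR-721 turned to 0.75. One signal lay outside the comparisons: the probe of the gammaherpesvirus miRNA mghv-miR-M1-2 was detected on 12 of 12 arrays, with a mean of -3.59, at the 53.1 percentile of the tested mouse miRNAs. Its group means were -4.43 in control and -3.81 in Dicer-deleted FO cells and -2.81 and -3.32 in the same MZ cells. Of the 10 viral miRNAs, 4 were detected on at least 1 array.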

How the results depend on the processing

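Signal over background and the few arrays limit these results: named miRNAs kept direction and side of the threshold in 9990 cases, moved in 803, gained a call in 200, lost it in 56 and reversed in 3, and called lists kept theirs in 522, lost it in 143 and reversed in 3. Of the 326 named miRNA results only 3 were called in the main fit, so most kept cases are results that stayed uncalled. The 56 losses and 3 reversals all concern those 3 calls. Further lists passed under other settings: 17 calls in 9 of 35 for genotype in MZ and 26 in 16 of 35 for MZ against FO Dicer-deleted cells, which had none. Alternatives without both MZ replicate 1 arrays or with scan as a block were chosen after seeing the data. Where no cause is given, the cause was not tested.

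For MZ against FO controls, limma called 1 miRNA without scaling, with normexp, without a filter, with a floor 2 times lower, with the mean of log2 over probes, with the brightest probe and with the files' total gene signal. It called 0 with quantile normalization, with a floor 2 times higher, with only the 43 miRNAs detected on all 12 arrays, with the deposited log2 values, with only the groups compared, within slide 2, and without both MZ replicate 1 arrays, also when scaled anew (171 tested); at an unadjusted p under 0.05 these had 21, 23, 6, 23, 14, 3, 20 and 25. It called 36 with the replicate block, 29 within slide 1, 20 with array weights, 14 with scan as a block, 12 with slide as a block, and 11 with slide as a block without both MZ arrays. For genotype in FO it called 2 with the percentile over all probes, 1 with the files' total gene signal, 8 with the replicate block, 19 within slide 1, 57 with array weights (40 lower), and 29 (25 lower) with slide as a block without both MZ arrays. MZ against FO in Dicer-deleted cells gave 1 with total gene signal. Array weights gave 6 for the interaction and 9 for the mean genotype difference. The replicate block changed no other count of called miRNAs. For MZ against FO Dicer-deleted cells, whose numbers were not treated as pairing, it gave 0 (13 unadjusted). There camera with the block called the miR-23-27-24 clusters (adjusted p = 0.00442).

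The correlation of genotype differences was -0.57 with slide as a block, -0.54 with scan as a block, 0.23 with array weights, 0.28 without both MZ replicate 1 arrays and 0.25 when scaled anew. The pooled difference in summed signal was -0.00826 with normexp, -0.39 relative to small RNA controls (exact permutation p = 0.085), -0.16 without the 5 brightest miRNAs, -0.11 without miR-680 to miR-721 and -0.31 within slide 1, and that in detected miRNAs -19.5 within slide 1. The unscaled FO median was -0.71 with total gene signal, -0.90 without miR-680 to miR-721 and -0.0841 within slide 2.

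With normexp, mmu-miR-139-5p (0.54), mmu-miR-28 (0.75) and mmu-miR-200c (0.73) reversed between MZ and FO controls, as all tested miRNAs shifted to a median of 0.69; its offset of 50 lies near the 75th percentile of MZ control replicate 1, 49.3. Within slide 2, with 1 array in most groups, the mean genotype difference reversed for let-7 (0.50) and B-cell roles (0.58) and was 0 for miR-680 to miR-721.

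Leaving out 1 array at a time gave 0 to 4 miRNAs for MZ against FO controls, 0 to 4 for genotype in FO, 0 to 0 in MZ, 0 to 0 for MZ against FO Dicer-deleted cells, 0 to 1 for the interaction and 0 to 2 for the mean genotype difference. The correlation ran from -0.49 to 0.71, summed signal from -0.39 to 0.48, detected miRNAs from -15.7 to 25.1, and the unscaled median from -0.84 to -0.42 in FO and -0.13 to 1.29 in MZ.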

Other observations

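Several further groups were described by few members. Both miR-26 members were lower in control MZ than in control FO cells, miR-26a by -2.56 (SE 1.24, adjusted p = 0.326) and miR-26b by -2.65 (SE 1.16, adjusted p = 0.326), or by -1.01 and -1.53 without both MZ replicate 1 arrays, and with genotype in FO cells they differed by -0.89 (SE 1.24) and -1.35 (SE 1.16). Of the miR-181 family, miR-181a and miR-181c were tested, the latter not well above background on any MZ array. MiR-34a, a p53-induced miRNA that blocks B-cell maturation when raised, was detected on 2, 2, 0 and 1 arrays of control FO, Dicer-deleted FO, control MZ and Dicer-deleted MZ cells and was not tested.

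MiRNAs of other tissues were mostly not well above background. Of 27 miRNAs of the imprinted Dlk1-Dio3 region, 2 were tested, and miR-370 was 0.66 higher after deletion in FO and 0.65 in MZ cells (SE 0.31 each; mean 0.66, SE 0.22, adjusted p = 0.859). Of 14 embryonic stem cell miRNAs only miR-290-5p was tested, differing by 0.34 (SE 0.51) with genotype in FO cells. Of 14 miRNAs restricted to other tissues only miR-200c was tested, of 4 in the miR-221, miR-222 and miR-146 families only miR-146a, and none of 5 in the miR-99/100 and miR-125 families was detected on any array.

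The tests of this and the next paragraph were chosen after their results were seen. Over miRNAs, the MZ against FO difference of controls ran with the genotype difference in FO cells. The Pearson correlation was 0.78, against a mean of 0.44 in simulations of unchanged groups, and both differences use the same control FO arrays. Not all control FO arrays stood apart from the other groups. On the first principal component of the scaled signals, replicates 2 and 3 lay lowest, at -12.62 and -9.99. Control FO replicate 1 lay at 0.18, inside the range of the other groups. The covariance was 0.52, where simulated unchanged groups gave a mean of 0.29 and an upper bound of their 95% interval of 1.45, so that over all arrays the shared controls cannot be told apart from a shared effect. Within slide 1 it was 0.43, close to that over all arrays, which argues against slide, and it exceeded the upper bound of 0.21 that shared controls alone gave there. The slide 1 simulation drew on few arrays. Both control FO arrays of slide 1 were also its brightest, with log2 summed signals of 16.77 and 16.26 against 15.39 to 15.84. A property of control FO cells may be a source, as a hypothesis. Array brightness, not tested for this pattern, cannot be told apart from it, and no other control FO arrays were used here.

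The replicate 1 arrays stood apart from the others of their groups, and both MZ ones most. Less labelled RNA on both MZ arrays is a candidate explanation, as the small RNA control signal of the higher of both lay -1.67 log2 units from the lowest other array. The log2 signal of the bright corner control spots was also lowest on both, at 4.96 (control) and 6.81 (Dicer-deleted). It was 8.47 to 10.16 on slide 1 and 12.11 to 13.29 on the other 3 slide 2 arrays. A low signal of the whole array thus cannot be told apart from less labelled RNA. Apart from both dim arrays, the slides thus differed in the bright corner signal. Hybridisation and scan cannot be told apart as its source, since the slides were scanned separately. By the probe ratios, a difference in hybridisation between the slides stays open. The long over short probe ratio of 1 control RNA on the highest of the other 3 slide 2 arrays lay -0.32 from the lowest slide 1 array. Those of 4 others overlapped. For the 1 RNA that did not, both MZ replicate 1 arrays lay inside the range of slide 1. For each of the 4 others both lay outside it. They lay above it for control RNA hur_6 (1.74 and 1.80 against 0.70 to 1.28) and below it for hur_4 (1.20 and 1.10 against 1.42 to 2.01). Scan stays open too: MZ control replicate 1 lay -2.54 from the lowest other array of its scan in log2 summed signal, but it lacks the low-gain scan, and MZ Dicer-deleted replicate 1 was alone in its scan. What these control RNAs are is not given in the sources used here, and no biological explanation was tested.

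The tests on other splits of the samples were planned before the data were examined. For MZ against FO controls, 1 of 10 splits of the 6 arrays gave as many miRNAs as the real one (3, highest other 1), and with the replicate block 1 of 4 splits that part every pair (36, highest other 0). For genotype in FO cells 3 of 10 splits gave as many at an unadjusted p under 0.05 (11, highest other 27), and with the block 1 of 4 at the adjusted threshold (8, highest other 0). For MZ against FO Dicer-deleted cells 5 of 10 did (3, highest other 16). For genotype in MZ cells, where the real count is 0, 10 of 10 did by construction, which says nothing about chance; the highest other split, with 47, put both dim replicate 1 arrays on one side, which points to a structure of the samples, and slide 1 alone gave 6. These designs have too few splits for a share under 0.05. For the interaction 42 of 100 drawn splits (10, highest other 78) and for the mean genotype difference 37 of 100 (9, highest other 77) gave as many in the fit without the block, over splits that ignored the pairs. With the replicate block and an unadjusted p under 0.05, 5 of the 32 splits that part every pair gave as many for the interaction (26, highest other 44) and 4 of 32 for the mean genotype difference (27, highest other 44), a test chosen after the data were examined. Chance was not excluded for either. Groups of 3 arrays did not overlap for 36 of 162 miRNAs in MZ against FO controls and 33 for genotype in FO. The counts were 3 for genotype in MZ and 11 in MZ against FO Dicer-deleted cells. Chance gives 10% only for miRNAs chosen without regard to group. Those tested were detected on all 3 arrays of at least 1 group. The MZ groups could bring in few, with 45 and 70 detected on their replicate 1 arrays. MiRNAs of an array also deviate together, so these counts are no evidence against chance.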
